A study of Mus musculus with 39 samples.

How the data were processed

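Per the labels, quadriceps muscle of male and female C57BL/6 mice was snap frozen, RNA was isolated and sequenced at one time for all mice, libraries were made from messenger RNA with a stranded TruSeq kit, and paired-end reads of 75 bases were produced on a HiSeq instrument. Per the submitters' processing notes, STAR 2.5, featureCounts, Subread 1.5.3, edgeR 3.20.8 and the mouse genome build mm10 were used, without a stated order. Handling of strand and reads with more than 1 place in the genome is not given, so overlapping or closely related genes are less certain. The deposited table holds raw counts per gene, not normalised, for 39 libraries and 52636 genes, as whole numbers, and 21205 of the genes had 0 counts throughout. Identifiers matched the reference annotation for 52403 genes without the version suffix (49035 with it). Identifiers replaced 27 symbols that had turned into bare numbers. Among 196 genes that shared a symbol with another, the one with the most counts kept it and the others were named by identifier.

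Groups were taken from the labels (sex, time, treatment). No sequencing batch and no pairing of mice is given in the labels, so no blocking term was used. Replicate numbers are names only. The tumour label differs between early (KPC) and late (KPC with vehicle) mice. Whether early mice or controls had injections is not given in the sources used here. The labelled sex was checked in each library with Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Repeated libraries were looked for within groups by the chi-square per degree of freedom of counts over 14141 genes, which ran from 13.3 to 473 in 57 pairs.

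Genes passing edgeR's filterByExpr by group (16246) were fitted over all 39 libraries in 1 model with a mean per group, TMM factors, robust dispersions and the quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3). The 15 comparisons were 10 between pairs of groups and 5 interactions. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The standard error is the size of the log2 change divided by the square root of F. CPM values use TMM factors, and log2 CPM a prior count of 2. All p-values are two-sided. Simulations of unchanged groups drew 20 sets of counts from the fitted dispersions.

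All 37 gene lists, 750 symbols of which 739 were matched, and the rule for naming genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over all lists of a comparison. The 75 list results described were picked after the results of all lists were seen. Of these, 5 kept their side of the threshold with an estimated correlation and 70 lost the call. Members in more than 1 list, such as Lcn2, Col1a1, Col3a1, Dcn and Lum, count in each. Scores are means of log2 CPM over the members of a list.

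Genes named in a comparison were the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between the compared groups, leaving out predicted genes, pseudogenes and immunoglobulin and T cell receptor segments. To these came up to 4 members of each described list by smallest p, 16 fixed genes (Fbxo32, Trim63, Foxo1, Mstn, Inhba, Acvr2b, Fst, Pdk4, Fkbp5, Cdkn1a, Myh4, Myh7, Ppargc1a, Serpina3n, Col1a1 and Col3a1), and for interactions up to 10 called genes. For control sex differences they were up to 6 per side outside the X and Y chromosomes and 5 sex genes. Not every gene picked is described.

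Alternatives were RLE factors, no low-count filter, a stricter one (at least 1 CPM in 4 libraries and on average), a non-robust fit, DESeq2 1.42.0, limma-voom with quality weights, dispersions from the compared libraries only, and leaving out each of the 39 libraries. Leaving out mitochondrial transcripts, slow sarcomere or adipocyte score covariates and a block for neighbouring title numbers were chosen after the data were seen. Splits of the compared libraries, the real one included, numbered 35 for a pair of groups and 60 drawn for an interaction. Library measures were compared by exact permutation tests.

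The test was tried on simulated data with 200 changed genes per comparison, 50 at each fold. Counts came from fitted dispersions shared by all groups, so groups of unlike spread were not tried. At 1.5, 2, 4 and 8-fold it recovered 22, 58, 90 and 98% in early males, 16, 54, 94 and 100% in early females, 10, 42, 96 and 94% in late males, 14, 68, 96 and 94% in late females, 10, 46, 86 and 98% for ACVR2B/Fc in males and 18, 54, 96 and 94% in females, with 2 to 9 false calls. Python 3.11.15 read tables and matplotlib 3.10.9 drew figures. Single transcripts, splicing, sequence variants and body or survival measures were not analysed here.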

Results

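Messenger RNA of the quadriceps was sequenced in 39 libraries, each from 1 C57BL/6 mouse, in 10 groups. Early control and early tumour-bearing (KPC) mice of each sex made up 4 groups of 4. Late control mice, late tumour-bearing mice given vehicle and late tumour-bearing mice given ACVR2B/Fc made up the other groups, with 4 mice each except for 3 late vehicle males. KPC is the label of the pancreatic cancer model, and ACVR2B/Fc is a soluble decoy made of the ligand-binding part of an activin receptor joined to an antibody Fc part. The labels give no time in days for early and late. Total counts per library ran from 20488181 to 38625361, with a median of 27678205. Of the genes listed, 16246 passed the low-count filter and were tested. Xist, the RNA of the inactive X chromosome, and 4 genes of the Y chromosome gave the labelled sex in all 39 libraries.

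All 16 control libraries lay between -46.59 and -32.21 on the first principal component, which held 30.2% of the variance. The 23 tumour libraries spread from -29.85 to 109.06. The second component held 8.6%. Among 60 exact permutation tests of library measures, the smallest adjusted p was 0.143, the level reached by the smallest exact p that 4 against 4 mice allow (0.0286, two-sided). TMM factors reached it in early tumour-bearing males (1.05 against 0.949 in controls), late vehicle males (1.2 against 0.996), ACVR2B/Fc males (0.879, against vehicle and against controls) and between early controls (1.02 in females, 0.949 in males).

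**Figure D1:**
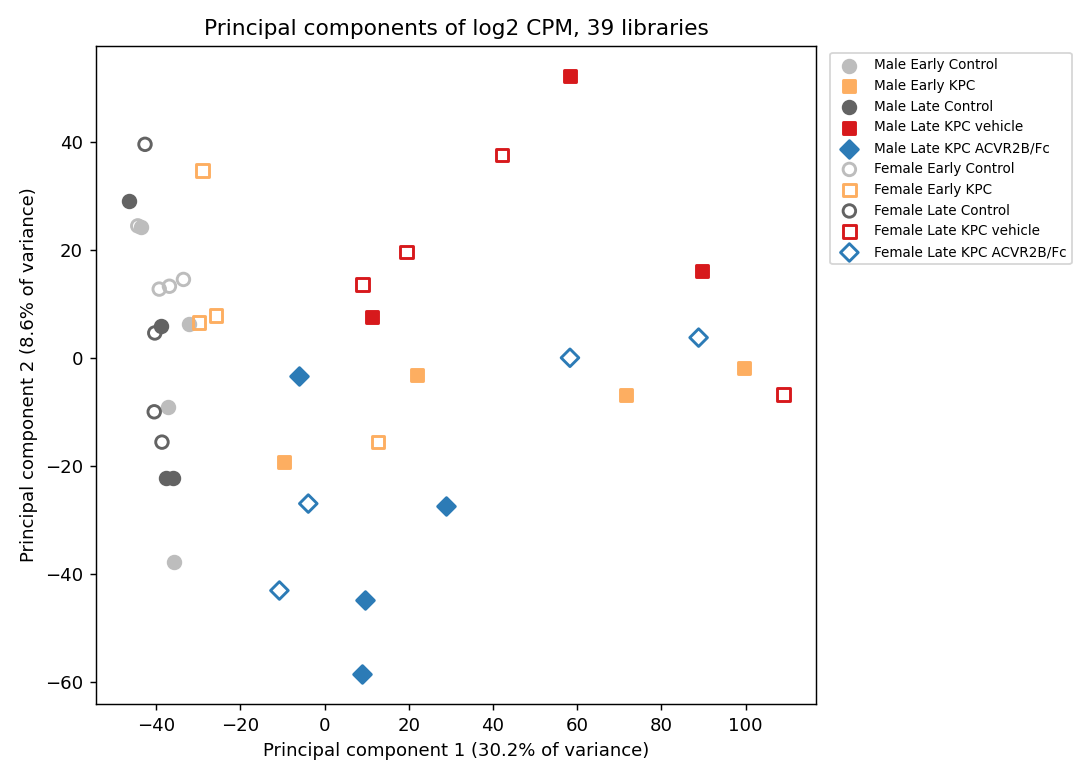
First and second principal components of log2 CPM, 1 point per library, coloured by group. All 16 controls lie below all 23 tumour libraries on the first component.

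**Figure D2:**
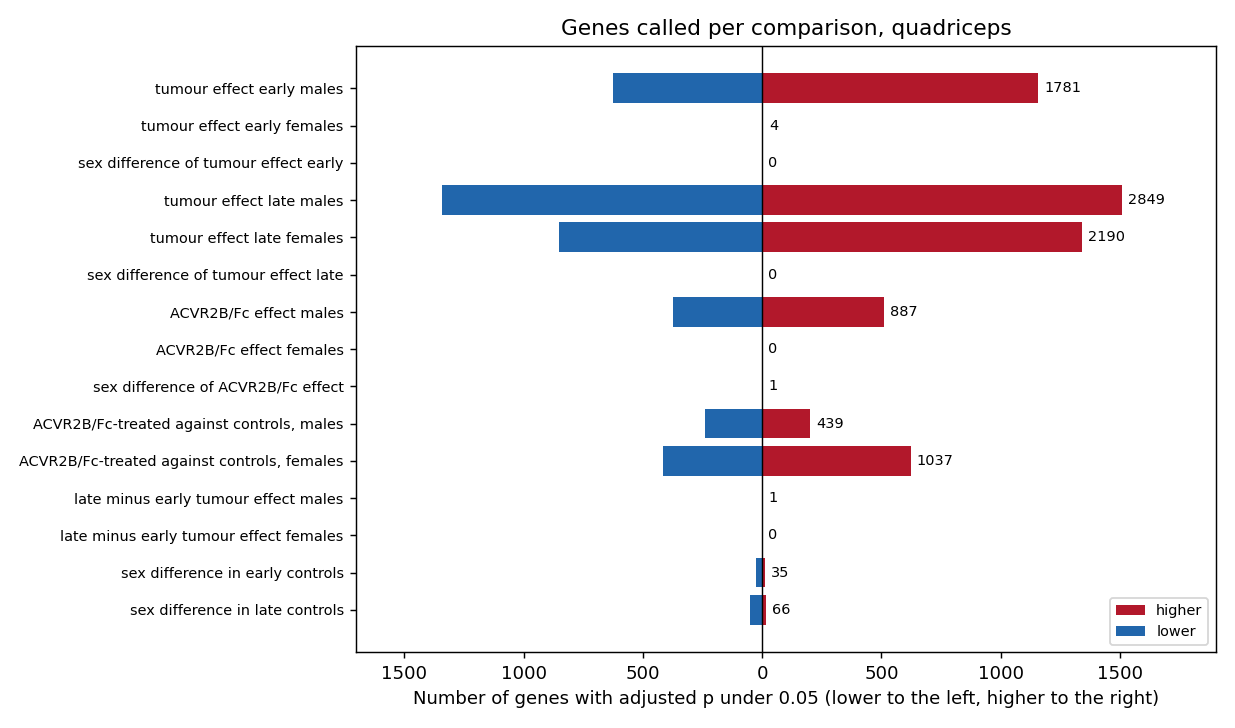
Genes called higher and lower (adjusted p under 0.05) in each comparison. Late vehicle males against controls gave 1508 higher and 1341 lower, early females 4 higher and 0 lower, and ACVR2B/Fc females 0.

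Early tumour-bearing males were compared with early control males (4 against 4) to ask what differed with the tumour at the time labelled early. Genes of neutrophils and of the acute phase were among those that rose most. S100a9, which encodes a subunit of the neutrophil protein calprotectin, stood at 22.2 ± 29.2 CPM (SD, n = 4) against 0.257 ± 0.194 CPM in controls (log2 change 6.42, SE 1.05, adjusted p = 0.0011). S100a8, which encodes its partner subunit, rose by 5.29 on the log2 scale, the acute-phase lipocalin Lcn2 by 4.65, and the metallothioneins Mt2 and Mt1 by 4.63 and 4.05. Il6ra, the interleukin 6 receptor, rose by 3.29. Among the largest falls, Nnat fell by 5.15, the adipocyte hormone Lep fell by 4.30, the fatty acid desaturase Scd1 fell by 3.47 and the muscle-secreted Ostn fell by 3.25. Col3a1, a fibrillar collagen of connective tissue, stood at 20.8 ± 27.6 CPM against 220 ± 75 CPM (log2 change -3.42, SE 0.85, adjusted p = 0.017), and Col1a1 fell by 2.94.

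Some genes of protein breakdown rose in early tumour-bearing males. Trim63 (chromosome 4, 134315120 to 134329629, mm10) and Fbxo32, both muscle ubiquitin ligases induced in atrophy, rose by 2.93 (SE 0.71) and 2.54 (SE 0.67). Fbxo32 was 973, 861, 5890 and 5250 CPM in replicates 1 to 4, replicate 2 within the controls (368 to 883). Of 31 proteasome subunits measured, 20 were called higher, 0 lower and 11 not called, with 29 higher when adjusted over the list alone (camera adjusted p = 7e-10, 0.47 with estimated correlation). Psma7 and Psmd4 rose by 1.49 and 1.51. Of 22 autophagy and lysosome genes, 8 rose and 14 were not called, with 14 higher adjusted over the list alone (camera adjusted p = 2e-04, 0.47 with estimated correlation). The autophagosome gene Map1lc3b rose by 1.10 and the mitophagy receptor Bnip3 by 1.69. Of 16 FoxO signalling genes, 6 rose, 1 fell and 9 were not called (6 higher and 2 lower adjusted over the list alone), and the list did not pass its test (camera adjusted p = 0.065, 0.47 with estimated correlation, but camera adjusted p = 0.043 without tumour-bearing replicate 4). Its members Foxo1, a transcription factor of atrophy genes, and Eif4ebp1, a brake on translation, rose by 1.84 and 3.22.

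Some genes of hormone and cytokine responses also rose in these early males. Of 20 glucocorticoid response genes, 9 rose and 11 were not called, with 11 higher adjusted over the list alone (camera adjusted p = 1.2e-06, 0.32 with estimated correlation). Fkbp5, a chaperone partner of the glucocorticoid receptor, rose by 2.62 (SE 0.52) and the transcription factor Klf15 by 1.35. Of 25 genes of the IL-6, STAT3 and acute phase list, 6 rose and 19 were not called, with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0013, 0.47 with estimated correlation). Osmr, the oncostatin M receptor, rose by 1.26 and the shared receptor chain Il6st by 0.71. Cdkn1a, a cell cycle inhibitor, rose by 3.19. Of 31 ribosome biogenesis and translation genes, 11 rose and 20 were not called, with 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.5e-06, 0.47 with estimated correlation), among them Wdr43 (1.19) and Npm1 (1.20).

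Most matrix genes and a few mitochondrial ones were called lower in early tumour-bearing males. Of 31 extracellular matrix genes, 0 rose, 19 fell and 12 were not called, with 1 higher and 23 lower adjusted over the list alone (camera adjusted p = 5.4e-15, 0.19 with estimated correlation). The crosslinking enzyme Loxl2 fell by 2.55, the basement membrane gene Nid1 fell by 1.30 and the protease Mmp2 fell by 1.57. Of 22 TCA cycle and pyruvate dehydrogenase genes, 8 fell and 14 were not called, with 18 lower adjusted over the list alone (camera adjusted p = 7.2e-08, 0.47 with estimated correlation), including Idh3a (-1.0). Of 74 nuclear-encoded oxidative phosphorylation genes, 5 fell and 69 were not called, with 52 lower adjusted over the list alone (camera adjusted p = 5.4e-15, 0.47 with estimated correlation). Cycs, which encodes cytochrome c, and Ndufs1 each fell by 0.99.

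Markers of other cell types moved with these groups in early males. Of 12 neutrophil markers, 11 rose and 1 was not called, with 11 higher adjusted over the list alone (camera adjusted p = 2.5e-11, 0.19 with estimated correlation). Of 6 erythroid markers, 3 rose and 3 were not called, with 5 higher adjusted over the list alone (camera adjusted p = 2e-04, 0.41 with estimated correlation), and the haem synthesis gene Alas2 rose by 2.12. Of 12 fibroblast and fibro-adipogenic markers, 10 fell and 2 were not called, with 11 lower adjusted over the list alone (camera adjusted p = 9.1e-10, 0.19 with estimated correlation), among them Dpt (-2.05) and Cd34 (-0.99). The adipocyte score was 3.95 ± 0.971 against 5.45 ± 0.821 in controls (exact permutation p = 0.0857, two-sided, adjusted p = 0.302). The 10 genes with the most counts took 21.7% ± 3.64 of all counts against 27% ± 0.336 (exact permutation p = 0.0286, two-sided, adjusted p = 0.143). The activin pathway genes Mstn (0.64, adjusted p = 0.32), Inhba (-0.80, adjusted p = 0.42), Acvr2b (-0.52, adjusted p = 0.18) and Fst (-0.95, adjusted p = 0.12) were not called, nor was the fast myosin Myh4 (-0.56, adjusted p = 0.24).

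By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, early tumour-bearing males differed from controls in 1781 genes, 1157 higher and 624 lower, of which 840 changed at least 2-fold. The count was 79, 311 and 3788 without tumour-bearing replicates 4, 3 and 1, and 1047, 574, 614 and 473 without control replicates 1, 2, 3 and 4. It was 764 with no low-count filter, 106 with dispersions from the compared libraries only, 150 with the adipocyte score as a covariate, 2766 with the slow sarcomere score as a covariate and 3002 by limma-voom. Of the 56 genes named by rule and called, 12 kept the call whichever library was left out: S100a9, S100a8, Mt2, Mt1, Fkbp5, Osmr, Slc4a1, Loxl2, Nid1, Mmp2, Col5a2 and Cxcr2. With dispersions from the compared libraries only, 42 of the 56 lost it, Nid1 among them, and 11 kept it in every fit. Without tumour-bearing replicate 4, 43 lost it (adjusted p from 0.052 to 0.22), without replicate 3, 31 (0.051 to 0.14), and without replicate 2, 8 (0.051 to 0.074). Without control replicates 4, 2, 3 and 1, the losses were 23 (0.051 to 0.078), 18 (0.055 to 0.14), 13 (0.055 to 0.083) and 7 (0.05 to 0.094).

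The same question in early females (4 tumour-bearing against 4 controls) gave 4 genes, all higher. Osmr (ENSMUSG00000022146.12, chromosome 15, 6813577 to 6874969) stood at 20.7 ± 5.5 CPM (SD, n = 4) against 10.2 ± 0.821 CPM (log2 change 1.02, SE 0.19, adjusted p = 0.033). The other genes, named here because the count is small and chosen after their values were seen, were Tmem252 (3.39 ± 3.21 against 0.336 ± 0.195 CPM, adjusted p = 0.0285), Dscaml1 (0.314 ± 0.111 CPM against 0 counts in all 4 controls, adjusted p = 0.0285) and Scgb3a1 (0.634 ± 0.251 against 0.00984 ± 0.0197 CPM, adjusted p = 0.0322). All 4 were also called higher in early males and in late females. The atrophy ligases Trim63 (0.93, adjusted p = 1) and Fbxo32 (0.39, adjusted p = 1) and the receptor partner Fkbp5 (1.06, adjusted p = 1) were not called.

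Of the lists, the neutrophil markers of early females kept their call under every list test: 0 of 12 were called over all genes, but 9 were higher adjusted over the list alone (camera adjusted p = 4.3e-21, 0.015 with estimated correlation). S100a9 was 4.84 (adjusted p = 0.073) and S100a8 4.44 (adjusted p = 0.086). For the 6 erythroid markers 0 were called and 2 were higher adjusted over the list alone (camera adjusted p = 1.7e-07, 0.16 with estimated correlation). Among 20 glucocorticoid response genes 0 were called and 1 was higher adjusted over the list alone, Ddit4 reaching 2.75 (adjusted p = 0.5). That list passed camera with all libraries (adjusted p = 0.00016, adjusted p = 0.61 with estimated correlation) but not without tumour-bearing replicate 2 (adjusted p = 0.46). The 31 extracellular matrix genes (camera adjusted p = 6.8e-10, 0.43 with estimated correlation) and the 12 fibroblast markers (camera adjusted p = 5.4e-07, 0.35 with estimated correlation) passed as lower, with 0 members called and 0 adjusted over the list alone.

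The edgeR count in early females was 4 (4 higher, 0 lower, with 563 genes at an unadjusted p under 0.05), against 23 by DESeq2 and 25 by limma-voom. It was 2 with dispersions from the compared libraries only, of which 0 were among the 4. It was 0 without any 1 of the 4 controls or tumour-bearing replicates 2 or 4, and 2 without tumour-bearing replicate 1. Osmr lost its call in all 7 of these fits, with adjusted p of 0.22, 0.16, 0.19 and 0.089 without control replicates 1 to 4 and 0.099, 0.21 and 0.066 without tumour-bearing replicates 1, 2 and 4.

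The difference between the sexes in the early tumour effect (females minus males) was tested directly, since 1781 calls against 4 do not show that the effects differ. The edgeR interaction called 0 genes (smallest adjusted p = 0.547, with 1469 genes at an unadjusted p under 0.05), as did DESeq2 and limma-voom with 0 each. As lists, the proteasome subunits had a median difference of -0.73 with 0 called and 0 adjusted over the list alone (camera adjusted p = 9.9e-10, 0.54 with estimated correlation). The oxidative phosphorylation genes had a median of 0.61, 0 called and 0 adjusted over the list alone (camera adjusted p = 7.1e-19, 0.54 with estimated correlation). Extracellular matrix genes had a median of 0.90, 0 called and 1 higher adjusted over the list alone (camera adjusted p = 1.3e-08, 0.54 with estimated correlation). Psma7 differed by -1.34 (SE 0.52, adjusted p = 0.55) and Loxl2 by 1.81 (SE 0.52, adjusted p = 0.55).

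Late tumour-bearing males given vehicle were compared with late control males (3 against 4) to ask what advanced disease changed. Mt2 stood at 247 ± 209 CPM (SD, n = 3) against 1.7 ± 0.781 CPM (SD, n = 4), a log2 change of 7.17 (SE 1.07, adjusted p = 0.00019), and Mt1 rose by 5.47. Chil3, a macrophage chitinase-like protein, rose by 7.11, the B cell chemokine Cxcl13 by 5.91, Lcn2 by 5.71, Cdkn1a by 4.94 and the acute-phase gene Serpina3n by 4.06. Nnat stood at 0.0306 ± 0.0531 against 19.2 ± 19.3 CPM. Further large falls were those of the RNA Foxo6os (-5.38), the potassium channel Kcng4 (-4.91), Lep (-4.67), Nrep (-4.52) and Ostn (-4.48). Fbxo32 rose by 2.75 (SE 0.70), Trim63 by 3.28 (SE 0.74), Foxo1 by 2.04 and Fkbp5 by 3.09. Myh4, the main fast myosin heavy chain, fell by 1.35, from 48500 ± 8870 to 19100 ± 15900 CPM. Vehicle replicate 2, at 37300 CPM, lay near the lowest control (37800) and replicates 1 and 3 at 11900 and 8100. The log2 change was -2.28 without replicate 2, and the call was lost without replicate 1 or 3. Inhba, the activin A subunit, fell by 2.11 (adjusted p = 0.046), while Mstn (-0.11, adjusted p = 0.89), Acvr2b (-0.41, adjusted p = 0.32) and Fst (-0.25, adjusted p = 0.73) were not called.

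Some genes of energy use and of the fast fibre machinery fell in late vehicle males. Of 74 oxidative phosphorylation genes, 23 fell and 51 were not called, with 49 lower adjusted over the list alone (camera adjusted p = 9.7e-16, 0.4 with estimated correlation), among them Ndufs1 (-1.28). Of 22 TCA cycle genes, 15 fell and 7 were not called, with 17 lower adjusted over the list alone (camera adjusted p = 2.2e-09, 0.34 with estimated correlation), Idh3a by -1.39 and the citrate synthase gene Cs by -0.95. Of 25 glycolysis and glycogen genes, 1 rose, 12 fell and 12 were not called, with 2 higher and 19 lower adjusted over the list alone (camera adjusted p = 2.8e-07, 0.32 with estimated correlation), including Pkm (-1.11) and Pfkm (-1.0). Of 19 fast sarcomere and calcium handling genes, 1 rose, 6 fell and 12 were not called, with 2 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0022, 0.43 with estimated correlation), including Tpm1 (-1.65) and Myl1 (-2.25). The share of counts from mitochondrial genes was 8.59% ± 2.53 against 16.1% ± 1.04 and that of the 10 genes with the most counts 17.96% ± 4.04 against 26.9% ± 0.237 (exact permutation p = 0.0286, two-sided, adjusted p = 0.143 for each).

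Part of the protein breakdown, stress and cytokine genes rose in late vehicle males. Of 31 proteasome subunits, 15 rose and 16 were not called, with 23 higher adjusted over the list alone (camera adjusted p = 2.4e-09, 0.4 with estimated correlation). Of 22 autophagy and lysosome genes, 11 rose, 2 fell and 9 were not called, with 12 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00024, 0.35 with estimated correlation), the lysosomal protease Ctsl rising by 1.98. Of 20 glucocorticoid response genes, 13 rose, 1 fell and 6 were not called, with 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.7e-08, 0.21 with estimated correlation). Of 25 IL-6, STAT3 and acute phase genes, 16 rose and 9 were not called, with 18 higher adjusted over the list alone (camera adjusted p = 2.4e-09, 0.21 with estimated correlation), including Myc (3.05), Osmr (1.27) and Stat3 (1.27). Of 24 genes of the unfolded protein and integrated stress response, 10 rose and 14 were not called, with 11 higher adjusted over the list alone (camera adjusted p = 5.1e-05, 0.21 with estimated correlation), including Xbp1 (1.34) and Manf (0.99).

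Genes that muscle switches on after loss of its nerve, and muscle regulatory genes, were partly higher in late vehicle males. Of 20 neuromuscular junction and denervation genes, 8 rose, 1 fell and 11 were not called, with 9 higher and 4 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.12, 0.43 with estimated correlation, but camera adjusted p = 0.0063 without vehicle replicate 3). The acetylcholine receptor subunit genes Chrna1 and Chrnb1 rose by 2.02 (SE 0.29) and 1.63 (SE 0.25), and the transcription factor Runx1 by 3.55 (SE 0.59). Of 19 myogenic and satellite cell genes, 8 rose, 1 fell and 10 were not called, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.029, 0.34 with estimated correlation), and the call was lost without control replicate 1 (adjusted p = 0.054) or vehicle replicates 1 (0.16) or 2 (0.078). Myog, a master regulator of myogenic differentiation, rose by 4.06 (SE 0.54). Of 15 polyamine and androgen response genes, 3 rose, 6 fell and 6 were not called, with 3 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.019, 0.32 with estimated correlation, and camera adjusted p = 0.072 without vehicle replicate 2). Amd1, which encodes an enzyme of polyamine synthesis, fell by 3.66 (SE 0.59), its close relative Amd2 fell by 3.78 and the spermine oxidase gene Smox fell by 3.36, while Sat1, an enzyme of polyamine breakdown, rose by 1.15. Amd1 and Amd2 have closely similar sequences, and how reads fitting both were counted is not given.

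Of 31 extracellular matrix genes in late vehicle males, 2 rose, 13 fell and 16 were not called, with 2 higher and 17 lower adjusted over the list alone (camera adjusted p = 0.00025, 0.43 with estimated correlation), including Lama2 (-0.89). Of 12 neutrophil markers, 8 rose and 4 were not called, with 8 higher adjusted over the list alone (camera adjusted p = 2.1e-05, 0.34 with estimated correlation), including S100a8 (5.33). Of 12 fibroblast markers, 5 fell and 7 were not called, with 8 lower adjusted over the list alone (camera adjusted p = 5.1e-05, 0.34 with estimated correlation), including Dpt (-2.01). The edgeR test called 2849 genes, 1508 higher and 1341 lower, 1468 of them at least 2-fold. The count was 401 and 1137 without vehicle replicates 3 and 1, and 1784 and 1699 without control replicates 1 and 4. With no low-count filter it was 1762 and by limma-voom 4530. Of the 73 genes named by rule and called, 27 kept the call whichever library was left out: Mt2, Chil3, Cxcl13, Lcn2, Mt1, Cdkn1a, Foxo1, Fkbp5, Serpina3n, Myc, Osmr, Map1lc3a, Lama2, Errfi1, Myog, Cdh15, Itga7, Myf6, Chrna1, Chrnb1, Runx1, S100a8, Cxcr2, Amd1, Amd2, Xbp1 and Manf. Without vehicle replicate 3, 44 lost it (adjusted p from 0.05 to 0.24), without vehicle replicate 1, 21 (0.053 to 0.13), without vehicle replicate 2, 1 (0.082), and without control replicates 1, 3 and 4, 3 (0.051 to 0.062), 2 (0.052 to 0.13) and 1 (0.06).

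Late vehicle females against late control females (4 against 4) asked the same of the other sex. S100a9 stood at 11.5 ± 9.95 CPM (SD, n = 4) against 0.164 ± 0.0956 CPM (log2 change 6.07, SE 1.07, adjusted p = 0.0024). Lcn2 rose by 5.78, Cxcl13 by 5.54, Mt2 by 5.14, the calcium sensor Doc2b by 4.65 and Mt1 by 4.56. Actc1, cardiac actin, fell by 4.29, Lep fell by 3.69, Scd1 fell by 3.30, Ostn fell by 2.72, Col3a1 fell by 2.5 and Thrsp, a lipid synthesis gene, fell by 2.49. Pdk4, which blocks pyruvate oxidation, stood at 2250 ± 1090 against 298 ± 205 CPM (log2 change 2.92, SE 0.61, adjusted p = 0.0059). Foxo1 rose by 2.42, Fkbp5 by 2.83, Cdkn1a by 3.11 and Serpina3n by 3.30. Mstn (1.19, adjusted p = 0.062), Inhba (-1.38, adjusted p = 0.14), Acvr2b (-0.36, adjusted p = 0.35), Fst (-0.33, adjusted p = 0.59) and Myh4 (-0.56, adjusted p = 0.23) were not called.

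Of 18 ubiquitin ligases of muscle atrophy in late vehicle females, 6 rose and 12 were not called, with 6 higher adjusted over the list alone (camera adjusted p = 0.04, 0.57 with estimated correlation). That list lost its call without control replicate 2 (adjusted p = 0.11) or vehicle replicates 1 (0.18) or 3 (0.06). Trim63 rose by 3.41 (SE 0.72), Fbxo32 by 2.47 (SE 0.67) and Cblb by 1.0. Of 22 autophagy and lysosome genes, 10 rose, 1 fell and 11 were not called, with 12 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00032, 0.57 with estimated correlation), including Bnip3 (1.87). Of 20 glucocorticoid response genes, 13 rose and 7 were not called, with 15 higher adjusted over the list alone (camera adjusted p = 2.4e-10, 0.22 with estimated correlation), including Cebpd (3.97) and Errfi1 (2.42). Of 25 IL-6, STAT3 and acute phase genes, 9 rose and 16 were not called, with 15 higher adjusted over the list alone (camera adjusted p = 4.7e-08, 0.22 with estimated correlation), including Osmr (1.47) and Il6ra (3.84). Of 29 fatty acid use genes, 6 rose and 23 were not called, with 6 higher adjusted over the list alone (camera adjusted p = 0.0051, 0.7 with estimated correlation), including Acot1 (3.97) and Ucp2 (1.22). This list lost its call without control replicate 4 (adjusted p = 0.075) or vehicle replicates 3 (0.08) or 4 (0.11).

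Of 74 oxidative phosphorylation genes in late vehicle females, 0 were called and 0 adjusted over the list alone, although the list as a whole passed as lower (camera adjusted p = 1.1e-05, 0.7 with estimated correlation, and camera adjusted p = 0.082 without vehicle replicate 1), Ndufb4 standing at -0.38 (adjusted p = 0.1). Of 31 extracellular matrix genes, 1 rose, 10 fell and 20 were not called, with 2 higher and 16 lower adjusted over the list alone (camera adjusted p = 0.00021, 0.7 with estimated correlation). Col6a1 fell by 1.96, while the crosslinking enzyme Lox rose by 2.11. All 6 erythroid markers rose, with 6 adjusted over the list alone (camera adjusted p = 1.1e-05, 0.22 with estimated correlation), Alas2 by 2.95 and Hbb-bs by 2.24. Of 12 neutrophil markers, 8 rose and 4 were not called, with 9 higher adjusted over the list alone (camera adjusted p = 4.4e-08, 0.22 with estimated correlation). Of 12 fibroblast markers, 5 fell and 7 were not called, with 9 lower adjusted over the list alone (camera adjusted p = 2.7e-05, 0.38 with estimated correlation), including Cd34 (-0.82).

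The edgeR test called 2190 genes in late vehicle females, 1340 higher and 850 lower, 1067 of them at least 2-fold. The count was 269 and 1245 without vehicle replicates 1 and 3, and 901, 1318, 942 and 1186 without control replicates 1, 2, 3 and 4. It was 1095 with no low-count filter, 777 with dispersions from the compared libraries only and 700 with the adipocyte score as a covariate. Of the 46 genes named by rule and called, 25 kept the call whichever library was left out: S100a9, Lcn2, Cxcl13, Mt2, Doc2b, Mt1, Trim63, Foxo1, Pdk4, Fkbp5, Serpina3n, Osmr, Il6ra, Bnip3, Map1lc3b, Alas2, Hbb-bt, Slc4a1, Hbb-bs, Lox, Acot1, Errfi1, Cebpd, S100a8 and Cxcr2. Without vehicle replicates 1 and 3, 19 (adjusted p from 0.061 to 0.18) and 10 (0.052 to 0.11) lost it, and without vehicle replicates 2 and 4, 2 (0.05 to 0.077) and 1 (0.062). Without control replicates 1, 2, 3 and 4, the losses were 8 (0.052 to 0.11), 2 (0.051 to 0.073), 6 (0.065 to 0.17) and 6 (0.054 to 0.099).

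**Figure D3:**
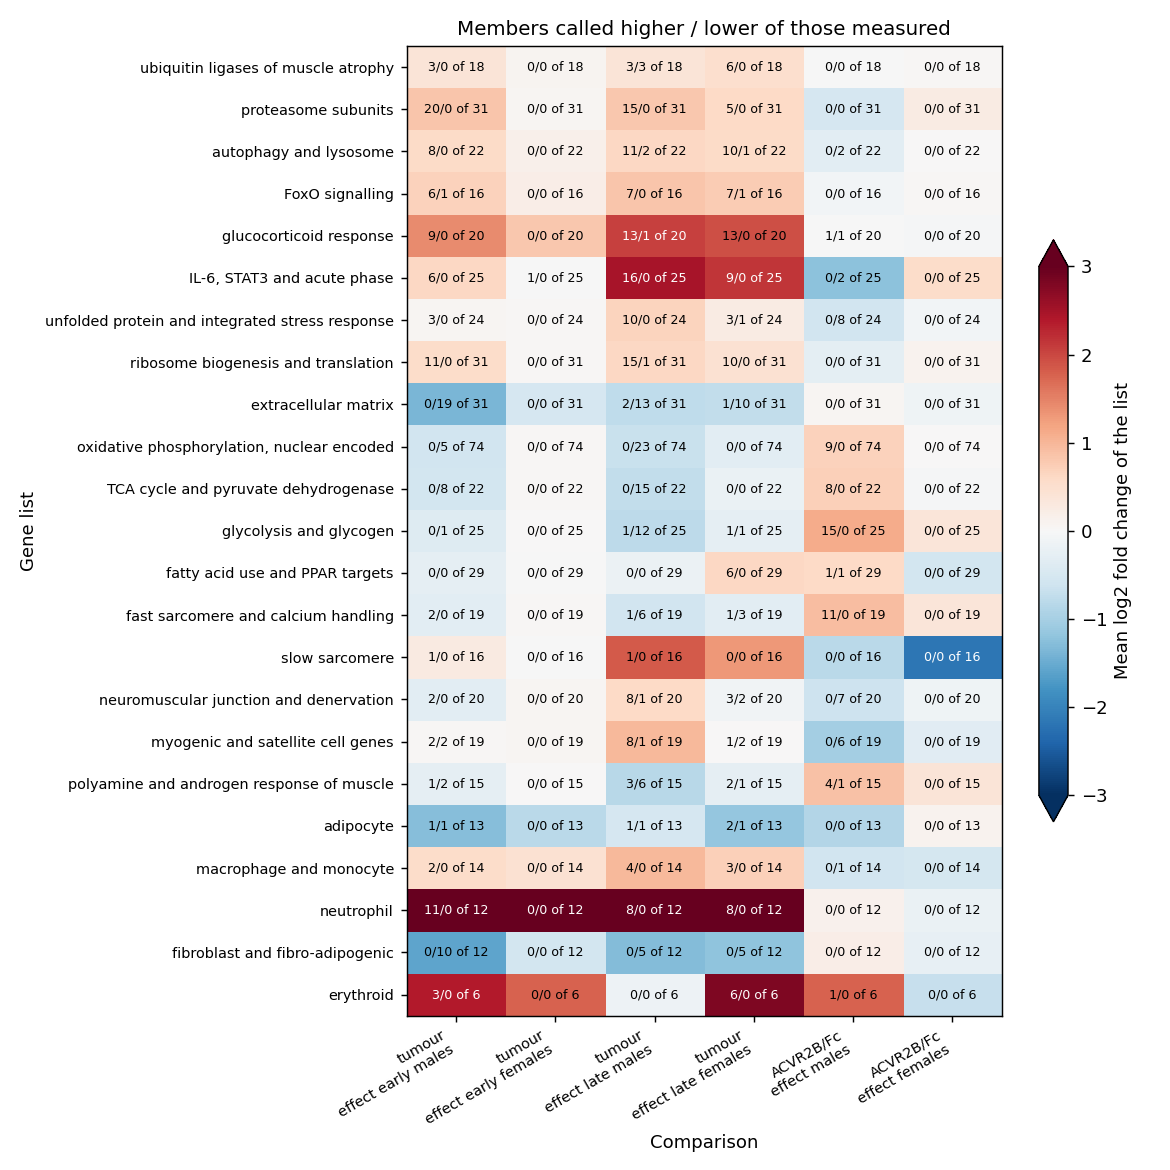
Mean log2 change of the members of described gene lists in pairwise comparisons, with the numbers called higher and lower of those measured in each cell. The colour scale ends at 3 on either side, and the neutrophil means of tumour-bearing mice against controls lie beyond it.

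Males and females shared 924 genes called the same way late in disease, 571 higher (124 expected from the sizes of the lists) and 353 lower (70.2 expected), and 1 called in opposite directions. Mt2, Lcn2, Cxcl13, Trim63, Fbxo32, Foxo1, Fkbp5, Cdkn1a, Serpina3n and Osmr rose in both, and Lep and Ostn fell in both. Across genes, which are not independent replicates, the log2 changes had r = 0.66 and rho = 0.67. The shared count was 1398 by DESeq2 and 1461 by limma-voom. It was 391, 583, 450 and 452 without female control replicates 1 to 4, 169 and 499 without female vehicle replicates 1 and 3, 571 without male control replicate 4, 403 and 175 without male vehicle replicates 1 and 3, and 1407 without male vehicle replicate 2. In males, 1005 genes were called the same way early and late (666 higher with 107 expected, 339 lower with 51.5 expected, 0 opposite).

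The interaction of sex with the late tumour effect (females minus males) called 0 genes by edgeR (smallest adjusted p = 0.0801, with 1083 genes at an unadjusted p under 0.05), 20 by DESeq2 and 13 by limma-voom. Erythroid markers had a median difference of 2.22, with 0 of 6 called but 6 higher adjusted over the list alone (camera adjusted p = 4.8e-07, 0.23 with estimated correlation), Hbb-bt standing at 2.47 (SE 0.81, adjusted p = 0.58). Myogenic genes had a median of -0.83, with 0 of 19 called and 1 lower adjusted over the list alone (camera adjusted p = 0.00023, 0.2 with estimated correlation). Myog differed by -3.09 (SE 0.70, adjusted p = 0.24). The edgeR count was 22 without male vehicle replicate 2, 1 without female vehicle replicate 3 and 1 without male control replicate 2. With dispersions from the compared libraries only, and with either the slow sarcomere or the adipocyte score as a covariate, it was 1.

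The late tumour effect was also set against the early one within each sex. Only the late tumour label names a vehicle, so stage is not separated from a possible injection. In males edgeR called 1 gene, Aif1l (ENSMUSG00000001864.13, chromosome 2, 31950139 to 31973442), with 660 genes at an unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma-voom. Aif1l, a relative of an actin-binding protein of macrophages, stood at 2.75 late (adjusted p = 0.00067) and -1.09 early (adjusted p = 0.12; difference 3.84, SE 0.68, adjusted p = 0.041). Of 20 neuromuscular junction and denervation genes 0 were called and 5 were higher adjusted over the list alone (camera adjusted p = 5.5e-05, 0.074 with estimated correlation), Chrna1 standing at 1.29 (SE 0.39, adjusted p = 0.82). Of 24 unfolded protein and stress response genes 0 were called and 6 were higher adjusted over the list alone (camera adjusted p = 4.6e-07, 0.07 with estimated correlation), Manf standing at 1.05 (SE 0.28, adjusted p = 0.43). The male count was 29 without late vehicle replicate 2, 2 without early tumour-bearing replicate 2 or late vehicle replicate 3, and 1 without late control replicate 2. It was 0, Aif1l losing its call, without early control replicates 1 to 4 (adjusted p = 0.089, 0.1, 0.088 and 0.086), early tumour-bearing replicates 1, 3 and 4 (0.064, 0.18 and 0.13), late control replicates 1, 3 and 4 (0.13, 0.078 and 0.19) and late vehicle replicate 1 (0.63). It was also 0 with no low-count filter and with the adipocyte score as a covariate.

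In females the late minus early contrast called 0 genes by edgeR (smallest adjusted p = 0.464, with 1700 genes at an unadjusted p under 0.05), DESeq2 and limma-voom. Among 20 glucocorticoid response genes 0 were called and 3 were higher adjusted over the list alone (camera adjusted p = 3.8e-07, 0.41 with estimated correlation), among them Errfi1 (1.91, SE 0.60, adjusted p = 0.46) and Pik3r1 (2.16, SE 0.64, adjusted p = 0.46).

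**Figure D4:**
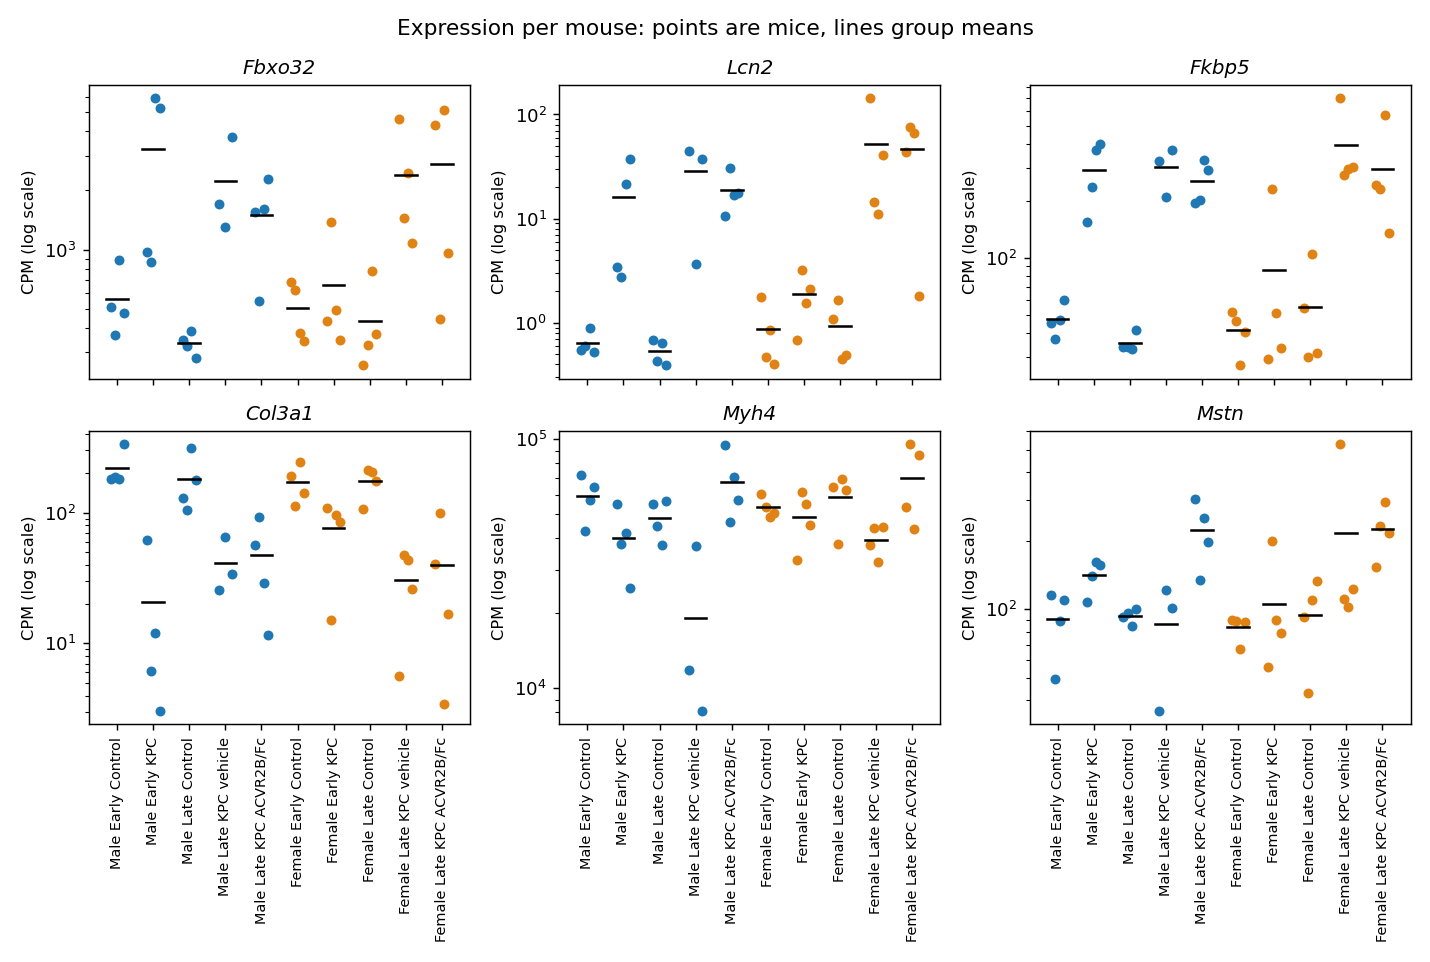
CPM of Fbxo32, Lcn2, Fkbp5, Col3a1, Myh4 and Mstn in each mouse on log axes, with points for mice and lines for group means. Mean Myh4 was 19100 CPM in late vehicle males and 67300 CPM in ACVR2B/Fc males.

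ACVR2B/Fc was compared with vehicle in late tumour-bearing males (4 against 3) to ask what blocking the receptor's ligands changed. Ucp3, a mitochondrial uncoupling protein of muscle, stood at 406 ± 128 CPM (SD, n = 4) against 41.6 ± 11.6 CPM (SD, n = 3), a log2 change of 3.29 (SE 0.61, adjusted p = 0.0027). Odf3l2 rose by 3.82, Tph1, an enzyme of serotonin synthesis, by 3.75, Amd2 by 3.42, the glutamate receptor partner Neto2 by 3.32 and Smox by 3.31. Aif1l stood at 1.76 ± 0.873 against 22.3 ± 12.6 CPM (log2 change -3.67, SE 0.51, adjusted p = 1e-04). The keratin Krt80 fell by 4.34, the lysosomal glycoprotein Gpnmb fell by 3.75, Tnnt2, the cardiac and embryonic troponin T, fell by 3.64, Acsm3 fell by 3.38 and Runx1 fell by 3.23. Fbxo32 (-0.58, adjusted p = 0.64), Trim63 (-0.59, adjusted p = 0.65), Foxo1 (0.45, adjusted p = 0.52), Fkbp5 (-0.25, adjusted p = 0.81), Mstn (1.36, adjusted p = 0.087) and Cdkn1a (-2.59, adjusted p = 0.051) were not called.

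Part of the fast fibre and energy genes rose with ACVR2B/Fc in males. Of 19 fast sarcomere and calcium handling genes, 11 rose and 8 were not called, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.5e-10, 0.15 with estimated correlation). Myh4 rose by 1.82 (SE 0.37), from 19100 ± 15900 to 67300 ± 20800 CPM (2.76 without vehicle replicate 2, call lost without vehicle replicate 1 or 3), and Tnnc2 by 1.38. Of 25 glycolysis and glycogen genes, 15 rose and 10 were not called, with 21 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.8e-17, 0.07 with estimated correlation), including Pgk1 (1.32), Pkm (1.31) and Gapdh (1.07). Of 22 TCA cycle genes, 8 rose and 14 were not called, with 19 higher adjusted over the list alone (camera adjusted p = 4.1e-12, 0.36 with estimated correlation), including Cs (0.91). Of 74 oxidative phosphorylation genes, 9 rose and 65 were not called, with 62 higher adjusted over the list alone (camera adjusted p = 2e-24, 0.45 with estimated correlation), including Ndufs4 (0.93). The 10 genes with the most counts took 27.6% ± 1.21 of counts against 17.96% ± 4.04 with vehicle (exact permutation p = 0.0286, two-sided, adjusted p = 0.143).

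Of 15 polyamine and androgen response genes, 4 rose with ACVR2B/Fc in males, 1 fell and 10 were not called, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00071, 0.078 with estimated correlation). Amd1 rose by 3.14 and Sms, the spermine synthase gene, by 1.29. Of 20 neuromuscular junction and denervation genes, 7 fell and 13 were not called, with 8 lower adjusted over the list alone (camera adjusted p = 0.049, 0.53 with estimated correlation). Chrna1 fell by 1.83 and Ncam1 fell by 1.63. This list lost its call without ACVR2B/Fc replicates 1 (adjusted p = 0.053), 3 (0.052) or 4 (0.14) or vehicle replicates 1 (0.088) or 2 (0.24). Of 19 myogenic genes, 6 fell and 13 were not called, with 7 lower adjusted over the list alone (camera adjusted p = 0.0027, 0.15 with estimated correlation), including Itga7 (-1.39) and Myog (-2.67). Of 24 unfolded protein and stress response genes, 8 fell and 16 were not called, with 1 higher and 11 lower adjusted over the list alone (camera adjusted p = 0.00017, 0.15 with estimated correlation), including Manf (-1.05).

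The edgeR test called 887 genes for ACVR2B/Fc in males, 512 higher and 375 lower, 450 of them at least 2-fold. The count was 92, 2307 and 119 without vehicle replicates 1, 2 and 3, and 262, 588 and 459 without ACVR2B/Fc replicates 1, 2 and 3. It was 19 with dispersions from the compared libraries only, 437 with no low-count filter, 1449 with the adipocyte score as a covariate, 1467 by DESeq2 and 2443 by limma-voom. Of the 41 genes named by rule and called, 13 kept the call whichever library was left out: Ucp3, Krt80, Gpnmb, Aif1l, Tnnt2, Runx1, Itga7, Myog, Chrna1, Ncam1, Chrnb1, Amd1 and Sms. Of these, Ucp3, Aif1l, Chrna1 and Amd1 kept it in every alternative fit, and 34 of the 41 lost it with dispersions from the compared libraries only. Without vehicle replicates 1 and 3, 27 (adjusted p from 0.054 to 0.26) and 22 (0.056 to 0.23) lost it. Without ACVR2B/Fc replicates 1, 2, 3 and 4, the losses were 5 (0.056 to 0.078), 8 (0.059 to 0.11), 2 (0.054 to 0.089) and 1 (0.055).

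The same comparison in females (4 against 4) called 0 genes by edgeR (smallest adjusted p = 0.327, with 1550 genes at an unadjusted p under 0.05), 8 by DESeq2 and 0 by limma-voom, and 3 by edgeR without ACVR2B/Fc replicate 1. Myh4 stood at 69900 ± 25200 CPM (SD, n = 4) against 39600 ± 5800 CPM (log2 change 0.82, SE 0.33, adjusted p = 0.46). Trim63 (0.05, adjusted p = 0.99), Fbxo32 (0.18, adjusted p = 0.95) and Mstn (0.05, adjusted p = 0.99) were not called either. The fast sarcomere list passed as higher, with 0 of 19 called and 4 higher adjusted over the list alone (camera adjusted p = 3.9e-06, 0.7 with estimated correlation), Tnni2 standing at 0.53 (SE 0.15, adjusted p = 0.33). The glycolysis list passed as higher with 0 of 25 called and 0 adjusted over the list alone (camera adjusted p = 0.00038, 0.7 with estimated correlation), Pkm standing at 0.77 (adjusted p = 0.36). The slow sarcomere list passed as lower with 0 of 16 called and 0 adjusted over the list alone (camera adjusted p = 2.9e-05, 0.7 with estimated correlation), its mean being -2.17. Myh7, the slow myosin, stood at 62.7 ± 57 against 571 ± 362 CPM (adjusted p = 0.62). Among late control females it ran from 0.223 to 614 CPM.

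The difference between the sexes in the ACVR2B/Fc effect (females minus males) had 1 gene called by edgeR, with 1568 genes at an unadjusted p under 0.05. Six5 (ENSMUSG00000040841.5, chromosome 7, 19094594 to 19098549), a homeobox transcription factor gene, stood at 0.51 in females (adjusted p = 0.552) and -1.81 in males (adjusted p = 0.00099), a difference of 2.31 (SE 0.41, adjusted p = 0.038). Of 29 fatty acid use genes 0 were called and 9 were lower adjusted over the list alone (camera adjusted p = 2e-10, 0.4 with estimated correlation), among them Ucp3 (-2.81, SE 0.76, adjusted p = 0.28). Of 74 oxidative phosphorylation genes 0 were called and 0 adjusted over the list alone, with a median of -0.71 (camera adjusted p = 6.5e-23, 0.4 with estimated correlation), Ndufs4 standing at -0.88 (adjusted p = 0.38).

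The count of 1 for that difference was 25 by DESeq2, 349 by limma-voom and 0 with dispersions from the compared libraries only. It was 52 without male vehicle replicate 2, 8 and 2 without female ACVR2B/Fc replicates 4 and 2, and 2 without male ACVR2B/Fc replicate 1. It was 0, Six5 losing its call, without female ACVR2B/Fc replicates 1 and 3 (adjusted p = 0.2 and 0.11), female vehicle replicates 1 to 4 (0.073, 0.075, 0.056 and 0.055), male ACVR2B/Fc replicates 2, 3 and 4 (0.072, 0.076 and 0.086) and male vehicle replicate 3 (0.23). So 887 calls in males and 0 in females came with 1 gene whose change was called different between the sexes.

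Genes called late in disease were followed into the ACVR2B/Fc comparison. In males, 625 of 2849 (21.9%) were called in the opposite direction, 245 of them higher with the tumour (34.8 expected from the sizes of the lists) and 380 lower (42.3 expected), and 1 was called the same way. The pairs included Myh4, Amd1 and Smox, which fell with the tumour and rose with ACVR2B/Fc, and Runx1, Myog and Chrna1, which rose and then fell. Both comparisons share the vehicle libraries, which alone makes them run opposite: the log2 changes had r = -0.65 across genes against -0.56 in 20 simulations of unchanged groups, and a covariance of -0.549 against -0.166. A split of the 3 vehicle males would leave 1 comparison with 1 vehicle library and was not made. Simulated dispersions were shared by all groups, so the part due to shared libraries stays open. The count of 625 was 61, 68 and 1878 without vehicle replicates 3, 1 and 2, 209, 364 and 351 without ACVR2B/Fc replicates 1, 2 and 3, 1008 by DESeq2 and 1890 by limma-voom.

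In females, 0 of the 2190 late tumour genes were called in the opposite direction by edgeR, with 3 by DESeq2 and 0 by limma-voom, and 1 by edgeR without ACVR2B/Fc replicate 1, while 1550 genes had an unadjusted p under 0.05 for ACVR2B/Fc. The log2 changes had r = -0.36 across genes against -0.50 in the simulations, and a covariance of -0.195 against -0.123. With vehicle females split so that each comparison had its own, 6 splits gave a mean r of -0.15 (from -0.39 to 0.17), against -0.47 unsplit on the same log2 CPM values. Against controls, 225 of the 2849 male genes (7.9%) and 626 of the 2190 female genes (28.6%) were still called in mice given ACVR2B/Fc. Lost calls do not equal a return to control levels: over these genes the median log2 change along the tumour effect was 1.03 with vehicle and 0.31 with ACVR2B/Fc in males, and 0.98 and 0.69 in females. The vehicle comparison picked the genes and both share the controls. Across all genes r was 0.59 in males and 0.78 in females, against 0.47 and 0.50 in the simulations, with covariances of 0.468 and 0.609 against 0.128 and 0.125.

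Tumour-bearing mice given ACVR2B/Fc were set against late controls to ask what remained. In males (4 against 4), Mt2 stood at 86.9 ± 26.2 CPM (SD, n = 4) against 1.7 ± 0.781 CPM (log2 change 5.66, SE 0.99, adjusted p = 0.0025). Lcn2 rose by 5.12, Tmem252 by 4.75, the stress-induced growth inhibitor Ddit4 by 4.67, Mt1 by 4.29 and Odf3l2 by 3.55. Scd1 fell by 4.30, Lep fell by 4.20, the amine oxidase Aoc3 fell by 2.71, Sncg fell by 2.29, Cd248 fell by 2.10 and Ddah1 fell by 2.01. Trim63 (2.69, adjusted p = 0.03) and Pdk4 (2.68) rose. Acvr2b fell by 1.0 (adjusted p = 0.034), and Fbxo32 (2.17, adjusted p = 0.07) was not called. Of 20 glucocorticoid response genes, 12 rose and 8 were not called, with 17 higher adjusted over the list alone. This list kept its call (camera adjusted p = 4.8e-23, 0.0052 with estimated correlation). Of 25 IL-6, STAT3 and acute phase genes, 4 rose and 21 were not called, with 14 higher adjusted over the list alone (camera adjusted p = 8.2e-09, 0.11 with estimated correlation). Of 31 extracellular matrix genes, 4 fell and 27 were not called, with 1 higher and 18 lower adjusted over the list alone (camera adjusted p = 4.9e-08, 0.29 with estimated correlation). Of 12 neutrophil markers, 6 rose and 6 were not called, with 9 higher adjusted over the list alone (camera adjusted p = 1.4e-11, 0.11 with estimated correlation).

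The edgeR count for ACVR2B/Fc males against controls was 439 (201 higher, 238 lower). It was 236 and 172 without control replicates 2 and 3, 202, 244 and 266 without ACVR2B/Fc replicates 1, 3 and 4, 277 with no low-count filter, 283 with the adipocyte score as a covariate, 791 by DESeq2 and 1767 by limma-voom. Of the 28 genes named by rule and called, 14 kept the call whichever library was left out: Mt2, Lcn2, Tmem252, Ddit4, Mt1, Foxo1, Pdk4, Fkbp5, Osmr, Myc, Mmp2, Klf15, S100a8 and S100a9. Without control replicates 1 to 4, the losses were 7 (adjusted p from 0.053 to 0.097), 8 (0.05 to 0.11), 12 (0.057 to 0.22) and 8 (0.059 to 0.14), and without ACVR2B/Fc replicates 1 to 4 they were 9 (0.061 to 0.14), 4 (0.051 to 0.093), 9 (0.064 to 0.12) and 11 (0.054 to 0.17).

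In females given ACVR2B/Fc (4 against 4 controls), Lcn2 stood at 46.9 ± 32.9 CPM (SD, n = 4) against 0.926 ± 0.579 CPM (log2 change 5.63, SE 1.02, adjusted p = 0.0029). Mt2 rose by 5.53, Tmem252 by 4.88, Cxcl13 by 4.83, Ddit4 by 4.51, Sox4 by 4.34, Trim63 by 3.46 and Fbxo32 by 2.65. Fbxo32 was 4320, 442, 5130 and 957 CPM in replicates 1 to 4, replicate 2 within the controls (258 to 775). The fatty acid elongase Elovl6 fell by 3.96, the fibroblast marker Pi16 fell by 2.82, Ostn fell by 2.82, Cd248 fell by 2.5, Acly fell by 2.01 and Col15a1 fell by 1.99. Of 31 proteasome subunits, 10 rose and 21 were not called, with 30 higher adjusted over the list alone (camera adjusted p = 2.5e-12, 0.33 with estimated correlation). Of 20 glucocorticoid response genes, 11 rose and 9 were not called, with 14 higher adjusted over the list alone (camera adjusted p = 5.7e-12, 0.11 with estimated correlation). Of 25 IL-6, STAT3 and acute phase genes, 12 rose and 13 were not called, with 20 higher adjusted over the list alone (camera adjusted p = 1e-09, 0.11 with estimated correlation). Of 31 extracellular matrix genes, 2 rose, 12 fell and 17 were not called, with 2 higher and 17 lower adjusted over the list alone (camera adjusted p = 3.9e-09, 0.25 with estimated correlation). Of 26 interferon and antigen presentation genes, 6 fell and 20 were not called, with 13 lower adjusted over the list alone (camera adjusted p = 2.2e-08, 0.25 with estimated correlation), among them Stat2 (-0.92) and Irf1 (-1.14). Of 12 fibroblast markers, 7 fell and 5 were not called, with 11 lower adjusted over the list alone (camera adjusted p = 2.1e-10, 0.11 with estimated correlation), including Cd34 (-1.25).

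The edgeR count for ACVR2B/Fc females against controls was 1037 (622 higher, 415 lower). It was 554, 344, 355 and 600 without control replicates 1 to 4, and 517, 2124, 109 and 1966 without ACVR2B/Fc replicates 1 to 4. It was 82 (31 higher, 51 lower) with dispersions from the compared libraries only, 634 with no low-count filter, 479 and 1761 with the adipocyte and slow sarcomere scores as covariates, 1729 by DESeq2 and 2948 by limma-voom. Of the 36 genes named by rule and called, 12 kept the call whichever library was left out: Lcn2, Mt2, Tmem252, Ddit4, Cd248, Foxo1, Osmr, Il6ra, Cd34, Mfap5, Mt1 and Errfi1. With dispersions from the compared libraries only, 26 of the 36 lost it, Osmr, Mt1 and Errfi1 among them, and 9 kept it in every fit. Without control replicates 1 to 4, the losses were 8 (adjusted p from 0.05 to 0.096), 10 (0.056 to 0.11), 10 (0.053 to 0.26) and 6 (0.052 to 0.08), and without ACVR2B/Fc replicates 1, 2 and 3 they were 10 (0.057 to 0.13), 1 (0.064) and 24 (0.052 to 0.29).

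Control females were compared with control males (females minus males, 4 against 4) to give the sex difference without a tumour. The 10 genes with the most counts took 25.5% ± 0.175 in females against 27% ± 0.336 in males early and 25.55% ± 0.946 against 26.85% ± 0.237 late, and mitochondrial genes 11.42% ± 1.93 against 16.14% ± 1.04 late (exact permutation p = 0.0286, two-sided, adjusted p = 0.143 for each). Some polyamine genes were lower in females. Amd1 stood at 173 ± 17.9 CPM (SD, n = 4) in early females against 933 ± 297 CPM in early males (log2 difference -2.43, SE 0.49, adjusted p = 0.015) and at 177 ± 41.6 against 1070 ± 138 CPM late (-2.60, SE 0.50, adjusted p = 0.0062). Odc1, which encodes the first enzyme of polyamine synthesis, differed by -1.62 early and -1.28 late, and Amd2 by -2.88 early and -2.32 late (adjusted p = 0.082, not called). Of 15 polyamine and androgen response genes, 3 were lower early and 12 not called, with 4 lower adjusted over the list alone (camera adjusted p = 0.00018, 0.04 with estimated correlation). Late, 2 were lower and 13 not called, with 6 lower adjusted over the list alone (camera adjusted p = 0.002, 0.1 with estimated correlation).

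Outside the X and Y chromosomes, the zinc transporter gene Slc30a2 (-4.82 early, -4.82 late), the complement gene C7 (-4.10, -4.96), Npnt (-2.77, -3.21) and Actr3b (-2.86, -2.72) were lower in control females, as was Tmem132b late (-4.07). Plod2, a collagen lysyl hydroxylase (1.76, 1.77), Gstm2 (1.22, 1.23) and Grb10, an adaptor that restrains insulin signalling (0.79, 1.19), were higher at both times. Il4ra (1.0) and Aldh7a1 (0.49) were higher early, and Ppp1r1a (1.17), Cradd (0.95) and Selenos (0.85) late. Xist stood at 247 ± 13 CPM in early females against 0.139 ± 0.0906 CPM in early males, and Ddx3y at 0.232 ± 0.193 against 84 ± 10.5 CPM.

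The edgeR test called 35 genes between early control groups (10 higher in females, 25 lower) and 66 between late ones (17 higher, 49 lower). The late count was 40 and 31 without female control replicates 1 and 3 and 38 and 43 without male control replicates 1 and 4. By DESeq2 the counts were 70 and 116, by limma-voom 174 and 661, and with dispersions from the compared libraries only 137 and 166. Early, 11 of 17 named and called genes kept the call whichever library was left out: Plod2, Slc30a2, C7, Actr3b, Npnt, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty and Odc1. The losses were 6 (adjusted p from 0.055 to 0.16), 5 (0.068 to 0.14), 6 (0.052 to 0.13) and 6 (0.071 to 0.15) without early female replicates 1 to 4, and 4 (0.062 to 0.17), 4 (0.072 to 0.14), 3 (0.18 to 0.24) and 6 (0.051 to 0.18) without early male replicates 1 to 4. Late, 13 of 18 kept it: Plod2, Grb10, C7, Slc30a2, Tmem132b, Npnt, Actr3b, Amd1, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. The losses were 3 (0.076 to 0.11), 2 (0.09 to 0.11), 5 (0.056 to 0.19) and 3 (0.059 to 0.1) without late female replicates 1 to 4, and 4 (0.072 to 0.21), 1 (0.051), 5 (0.071 to 0.16) and 4 (0.058 to 0.15) without late male replicates 1 to 4.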

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

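The tests of depth, blood content and fibre share in this part were chosen after the results they bear on were seen. In 207 sets of replicate values of 4 libraries, 20 held a library far from the others by Dixon's test, where chance gives about 1 in 20 (10.3).

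On the log2 CPM scale, the following libraries lay apart from the other 3 of their group. Trim63 was 7.4 in late male control replicate 3 (others 7.697 to 7.746). Mstn was 6.07 in early female control replicate 3 (6.469 to 6.487) and 9.05 in late vehicle female replicate 1 (6.67 to 6.944). Fkbp5 was 9.45 in the latter (8.104 to 8.248) and 5.38 in late male control replicate 4 (5.052 to 5.081). Cdkn1a was 4.62 in early female control replicate 1 (3.507 to 3.608) and Myh4 15.2 in late female control replicate 2 (15.94 to 16.08). Myh7 was 2.94 in early tumour-bearing female replicate 2 (8.163 to 8.654) and 5.34 in late vehicle female replicate 1 (9.427 to 9.747). Ppargc1a was 7.68 in early male control replicate 3 (5.361 to 5.7). Col1a1 was -0.703 in late vehicle female replicate 1 (2.944 to 3.697). Col3a1 was 3.91 in early tumour-bearing female replicate 2 (6.418 to 6.749) and 8.38 in early male control replicate 4 (7.491 to 7.556).

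Among library measures, total counts were 38625361 in ACVR2B/Fc female replicate 3 (others 28060000 to 29740000) and 20488181 in early tumour-bearing male replicate 1 (28960000 to 30300000). The 10 genes with the most counts took 27.2% in late male control replicate 4 (26.7 to 26.75), and mitochondrial genes took 11.33% in early female control replicate 1 (12.98 to 13.11). The first principal component was 12.7 in early tumour-bearing female replicate 2 (-29.85 to -25.8). The slow sarcomere score was 3.67 in late vehicle female replicate 1 (6.45 to 6.83), and the adipocyte score was 5.39 in early tumour-bearing male replicate 1 (3.26 to 3.62). In 2 genes the effect differed between groups by a test of the difference: Six5, whose ACVR2B/Fc change was 2.31 higher in females, and Aif1l, whose tumour effect in males was 3.84 higher late than early.

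Early in disease 1781 genes were called in males and 4 in females. Lower depth in females was argued against, since the female to male ratio of mean total counts was 1.02 (exact permutation p = 0.914). An unlike library inflating the female spread stays open: the 0 calls without tumour-bearing replicate 2, the female scoring highest, rest on 3 mice. The sex of the mice stays open: over genes called late in both sexes, the score above controls was 1.12 ± 0.55 (SD, n = 4) in males and 0.35 ± 0.28 in females (exact permutation p = 0.0571, two-sided). Female replicate 2 stood at 0.76 and the other females at 0.15 to 0.24, with a mean of 0.21 without it. The interaction called 0 genes, and the male count was 79 without tumour-bearing replicate 4, so a difference between the sexes was not shown.

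ACVR2B/Fc gave 887 calls in males and 0 in females. A different share of slow muscle was argued against as the whole cause, since with the slow sarcomere score as a covariate the male count was 995. A single vehicle library stays open: the lowest male count without one was 92, and the count without another was 2307. The sex of the mice stays open too: over genes called early in males, the score with ACVR2B/Fc minus that with vehicle was -0.40 in males (exact permutation p = 0.0857) and -0.05 in females (exact permutation p = 0.886). The difference between the sexes had a p of 0.344 over 2450 permutations.

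Neutrophil markers were higher in early tumour-bearing males, S100a9 at 22.2 CPM against 0.257 CPM, and 1 of the markers, Lcn2, is also on the acute phase list. A lower share of muscle fibre RNA stays open. The fibroblast score differed by -1.85 (exact permutation p = 0.0286, the smallest possible), but shares falling genes with the matrix list. More blood of unchanged make-up stays open: the neutrophil minus erythroid score was 1.63 above that of controls, with SDs of 1.96 and 0.79 (exact permutation p = 0.143). Entry of neutrophils into the muscle because of the tumour stays open as well and was not tested.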

How the results depend on the processing

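The covariate fits, title-number block and leaving out mitochondrial transcripts were chosen after seeing the data. RLE factors, a non-robust fit and leaving out mitochondrial transcripts kept all 15 counts of called genes within 1.5 times. Of 318 calls of named genes, 0 changed sign in an alternative, 114 were called in every one, 164 in all but leave-one-out fits, and 191 lost the call in at least 1 leave-one-out fit. Causes of the changes below were not tested. Fewer libraries are fewer mice, no filter tests more genes and the main fit pools groups of unlike spread.

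With no low-count filter the counts were 764 for the tumour in early males, 0 in early females, 1762 in late males and 1095 in late females, 437 for ACVR2B/Fc in males, 3 for its sex difference, 277 and 634 for ACVR2B/Fc males and females against controls and 0 for late minus early males. A stricter filter gave 2 in early females and 4 for the sex difference of ACVR2B/Fc. With the slow sarcomere score as a covariate they were 2766 in early males, 1 for the late sex difference, 2 for the sex difference of ACVR2B/Fc and 1761 for ACVR2B/Fc females against controls. With the adipocyte score they were 150 in early males, 11 in early females, 700 in late females, 1 for the late sex difference, 1449 for ACVR2B/Fc in males, 3 for its sex difference, 283 and 479 for ACVR2B/Fc males and females against controls and 0 for late minus early males.

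DESeq2 gave 23 in early females, 20 for the late sex difference, 1467 and 8 for ACVR2B/Fc in males and females, 25 for its sex difference, 791 and 1729 for ACVR2B/Fc males and females against controls, 3 for late minus early males, 70 and 116 for early and late control sex differences, 1398 for the overlap of the sexes and 1008 and 3 for reversal in males and females. Limma-voom gave 3002 in early males, 25 in early females, 4530 in late males, 13 for the late sex difference, 2443 for ACVR2B/Fc in males, 349 for its sex difference, 1767 and 2948 for ACVR2B/Fc males and females against controls, 0 for late minus early males, 174 and 661 for control sex differences, 1461 for the overlap and 1890 for reversal in males. Dispersions from the compared libraries only gave 106 in early males, 2 in early females, 777 in late females, 1 for the late sex difference, 19 for ACVR2B/Fc in males, 0 for its sex difference, 82 for ACVR2B/Fc females against controls, and 137 and 166 for control sex differences. They ended the call of 6 of 73 named genes in late males, 7 of 46 in late females and 8 of 28 for ACVR2B/Fc males against controls.

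Leaving out 1 library at a time gave 79 to 3788 in early males, 0 to 4 in early females, 401 to 4249 in late males, 269 to 3048 in late females, 0 to 22 for the late sex difference, 92 to 2307 for ACVR2B/Fc in males and 0 to 3 in females, 0 to 52 for its sex difference, 172 to 483 and 109 to 2124 for ACVR2B/Fc males and females against controls, 0 to 29 for late minus early males, 24 to 35 and 31 to 58 for early and late control sex differences, 169 to 1407 for the overlap, and 61 to 1878 and 0 to 1 for reversal in males and females. The early sex difference and late minus early females stayed at 0. Of the 75 list results, fry kept 53, weakened 20 and strengthened 2. Genes below the count filter were not tested.

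The titles carry numbers, and in 12 cases a tumour-bearing and a control mouse of one sex and time have consecutive ones. Their deviations from the group means had correlations of -0.13 to 0.11 across genes, against -0.23 to 0.25 in the other 48 combinations, so they did not deviate together. A fit with these numbers as a replicate block gave 1073 in early males, 0 in early females, 2260 in late males and 1392 in late females.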

Other observations

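Splits drawn for interactions were raised to 60 after results from smaller draws had been seen. Of the 2190 late female genes, 3.38% ran opposite in early males (23.1% of all genes), where 748 were called the same way. Of the 2849 late male genes, 26.1% ran opposite in early females (39.1% of all genes). With ACVR2B/Fc in males, 79% of the late female genes ran opposite (median -0.32 along the tumour effect, 125 called opposite and 11 the same), and with ACVR2B/Fc in females 64.5% of the late male genes did (median -0.10, 0 called either way). Over all genes tested the shares were 66.2% and 56.6%. Of the 1781 early male genes, 81.9% ran opposite with ACVR2B/Fc in males (median -0.38) and 52.3% in females (median -0.02), against 66.2% and 53.3% over all genes.

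A first hypothesis was that early females may already carry part of the late tumour pattern. Over genes called late in males, which share no mice with them, early tumour-bearing females scored 0.19 above their controls (SD 0.17 and 0.03, n = 4 each, 4 of 4 above all controls, exact permutation p = 0.0286, two-sided and the smallest possible), in line with the hypothesis. Replicate 2 stood at 0.45 and the mean without it was 0.11. A second was that ACVR2B/Fc may move late tumour genes of the other sex toward control levels. The scores with ACVR2B/Fc minus vehicle were -0.35 in males (exact permutation p = 0.143) and -0.15 in females (exact permutation p = 0.629), and together p was 0.156 over 2450 permutations, which leaves it open.

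Each count of called genes was set against other splits of the same libraries. Only 1 of 35 splits, the real one, gave as many genes for the tumour in early males (1781, highest other 749), early females (4, highest other 0), late males (2849, highest other 239) and late females (2190, highest other 1), for ACVR2B/Fc in males (887, highest other 211), for ACVR2B/Fc males (439, highest other 1) and females (1037, highest other 179) against controls, and for the sex difference of early (35, highest other 0) and late controls (66, highest other 4), so chance was excluded at that level. For early females this rests on 4 genes, a count that was 0 in 6 of 8 fits without 1 library, with no low-count filter and with the title numbers as a block. Since only the real split parts the sex genes, control counts were also taken without X and Y genes: 20 early (highest other 0) and 51 late (highest other 4), again only in the real split.

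For the other comparisons the splits could not weigh whether chance was at work. For ACVR2B/Fc in females all 35 splits gave at least the real 0, as every split must, so this decided nothing, but 12 gave more. The highest, 3262, set ACVR2B/Fc replicates 1 and 3 with vehicle replicates 1 and 3 against the rest, which points to a structure of these samples. In interactions the splits exchange labels within each pair of groups, so effects of tumour or treatment enter the difference and the counts are no measure of chance for it. With a real 0, 60 of 60 splits gave at least as many for the early sex difference (highest other 27), the late sex difference (highest other 2116) and late minus early females (highest other 774), which decided nothing either. In the last, the highest split exchanged all late control and vehicle mice. For the sex difference of ACVR2B/Fc 19 of 60 gave at least the real 1 (highest other 1032, with the female grouping named above), and for late minus early males 8 of 60 did (highest other 3215).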
